A study of Oryza sativa Japonica Group with 16 samples.

How the data were processed

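RNA from rice roots (Oryza sativa ssp. japonica, cultivar Selenio) was measured on 16 Affymetrix Rice Gene 1.0 ST arrays, which carry short oligonucleotide probes grouped into 1 probe set per annotated transcript cluster. Per the labels' protocols, the tissue was the part of adventitious roots 2 to 6 cm behind the tip, taken after 28 days in nutrient solution, and 100 ng of total RNA with an RNA integrity number of at least 9.5 was amplified and biotin-labelled with a 3' IVT Express kit. Such kits prime at the 3' end, while the array's probes lie along whole transcripts, and whether the kit is named correctly could not be settled from the sources used here. The time of germination before transfer differs between the sources: 7 days in the growth protocol and 14 days in the design text. Plants of the group named Plus_Si received 30 mg/L, given as silicic acid, and plants of the control group, named Minus_Si, received 3 mg/L, given as Si. Each group had 4 biological replicates, each a pool of roots of 5 plants from a shared pot, and each replicate was put on 2 technical arrays. The sources used here do not say whether every pool came from a pot of its own, so p-values measure the spread between these pools.

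The deposited values are intensity values on a linear scale, 1 per probe set and array. Per the submitters' processing notes the authors used RMA, a method that corrects background, sets the distributions of arrays equal and summarises probes, and per the file headers the values were exported from GeneSpring as antilog values. Versions and settings of these steps were not given in the sources used here. The deposited value table holds the exported intensity values rounded to whole numbers, from 2 to 22684, and 0 of its entries differed from the rounded export. The authors also deposited a ratio of Plus_Si over Minus_Si and a signed fold per probe set; the ratio was recomputed from the array values with 0 mismatches and is not otherwise used. Rounding is coarse for dim probe sets, where a step of 1 unit is a visible share of the value, so the unrounded export was run as an alternative.

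Intensities were taken to log2 with no pseudocount. The table holds 54922 probe sets. The 9728 control, spike-in, reporter, ribosomal RNA and intron or exon normalization probe sets were left out of the tests, which leaves 45194. Of these, 44377 carry 1 gene in the deposited annotation, 494 several and 323 no rice locus; 14324 were matched to 1 gene of the RefSeq table of assembly GCF_034140825.1, which was used for symbols only. Coordinates are those of the deposited annotation, on rice pseudomolecules of MSU release 6. No filter on dim probe sets was applied. The deposited annotation gives each probe set a cross-hybridisation type: 40759 tested probe sets have type 1, whose probes match 1 target, and 4435 have type 3, whose probes also match other sequences. Background was read from 23 antigenomic control probe sets, whose sequences have no rice target and which were not matched to probe sets by base content; the per-array median of these controls lay between 4.7 and 5 on the log2 scale, while the means of single controls ran from 1.56 to 9.39, so background is known only roughly for any one probe set. Where every array of a group lay under its own array's control median, the fold is given as at least the bright group's mean over the dim group's mean, with each dim value raised to that control median. Where only some arrays of a group lay under it, the fitted fold is given.

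The 2 technical arrays of a replicate were averaged before the fit, which makes 4 samples against 4. The difference Plus_Si minus Minus_Si was tested per probe set with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, and p-values were adjusted with the Benjamini-Hochberg method over all 45194 probe sets. A probe set is called changed at an adjusted p under 0.05. The 32 gene lists, the design, the rule for named genes and all but 1 of the alternatives were fixed before the data were examined. A list holds the probe sets for which a description in either of the deposited annotation columns matches a fixed pattern, or whose locus was fixed. Lists of at least 5 probe sets were tested with limma's camera, which compares a list with all other probe sets, with a preset correlation between genes of 0.01 and again with an estimated one, and adjusted over the 30 tested lists. Counts of changed members are given over all probe sets and adjusted over the list alone. Gene Ontology terms of the deposited annotation were tested with a one-sided Fisher's exact test among the 19085 tested probe sets that carry a biological process term, over 691 terms with at least 10 members.

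Genes were named by a fixed rule. It takes the 10 largest fitted differences in each direction among changed probe sets of 1 gene that had the same direction in both technical sets, did not overlap between the replicates of the groups and were not annotated as transposons; of several probe sets of a gene, the brighter. It also takes all silicon transporters and the fixed Casparian strip and suberin loci, and up to 4 changed members of every other list by size, or the 1 with the smallest p where none changed. Of the 145 named genes that changed, 97 kept their call when any 1 of the 8 samples was left out and 48 did not, and the text draws its examples from the former unless it says otherwise. The remaining members of the iron and phosphate lists, 4 lists of iron, methionine and photosynthesis genes and their members were chosen after the main comparison had been seen.

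The fit and camera were tested on simulated data with the real means and spreads, with 200 of 45194 probe sets changed: 50% of those changed by 0.5 on the log2 scale were recovered, 88% of those changed by 1, and 100% of those changed by 2 or 4, and 8 of 177 calls (4.52%) were false. Camera called the 1 shifted list and 0 unshifted lists. The simulated share of changes was smaller than in the data (6.55%), so recovery may differ there. Simulated noise was independent between genes, so the preset correlation of camera was not tested. Alternatives were each technical set alone, all arrays with the technical set as a term and the sample as a random block, the replicate number as a block, quantile normalization, median centring of arrays, the unrounded export, leaving out the dimmest 30% of probe sets, an intensity trend with robust variance, sample weights, a fold of at least 1.5 with an adjusted p or with an unadjusted p under 0.01, a plain equal-variance test, an estimated correlation in camera, leaving out each replicate, and, chosen after seeing the data, type 1 probe sets only. Technical sets 1 and 2 each hold all 8 samples once and were treated as batches. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.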

Results

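The series compared adventitious roots of rice supplied with 30 mg/L silicic acid (Plus_Si) with roots of control plants supplied with 3 mg/L Si (Minus_Si), to find the genes of the root segment behind the tip that respond to silicon supply. Rice takes up silicon actively and stores it in its shoot. The control solution still held silicon, so the comparison is one of a high with a low supply. The labels give one concentration as silicic acid and the other as Si, so their ratio is not known. There were 4 pools of roots per group with 2 arrays each, and the median intensity of the tested probe sets lay between 79 and 85 on all 16 arrays. The small number of pools limits the precision of every value.

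Of 12 probe sets for iron and metal uptake genes 9 rose in Plus_Si roots, and all 4 silicon transporter genes fell. Transcripts of OsNAS1, a nicotianamine synthase, were 80.5-fold higher with high silicon, and those of the silicon efflux transporters Lsi2 and Lsi3 were 5.24-fold and 7.81-fold lower. Of 28 probe sets for nitrogen transport and assimilation 9 rose, and of 39 for aquaporins 10 fell, though neither of these lists nor the iron list passed with an estimated correlation (adjusted p = 0.0909 for nitrogen, adjusted p = 0.589 for aquaporins and adjusted p = 0.0909 for iron). In total 2962 of 45194 probe sets (6.55%) changed, 1309 of them higher and 1653 lower in Plus_Si; 10113 had an unadjusted p under 0.05. Most changes were small, with a median absolute log2 difference of 0.51 among changed probe sets, while 176 rose and 210 fell by at least 2-fold. The median log2 difference of all tested probe sets was 0.019. The changed probe sets stood for 1287 distinct genes among the rises and 1582 among the falls. Within the technical sets, 1771 probe sets changed in set 1 (673 higher, 1098 lower) and 1192 in set 2 (547 higher, 645 lower). With the set as a term and the sample as a random block 4899 changed (2006 higher, 2893 lower). That fit took technical arrays as observations, while the groups differ between samples only, so its count can be too large. The total fell to 1911, 1937, 1666 and 1574 without Plus_Si replicate 1, 2, 3 or 4, and to 1928 and 1629 without Minus_Si replicate 2 or 3.

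**Figure D1:**
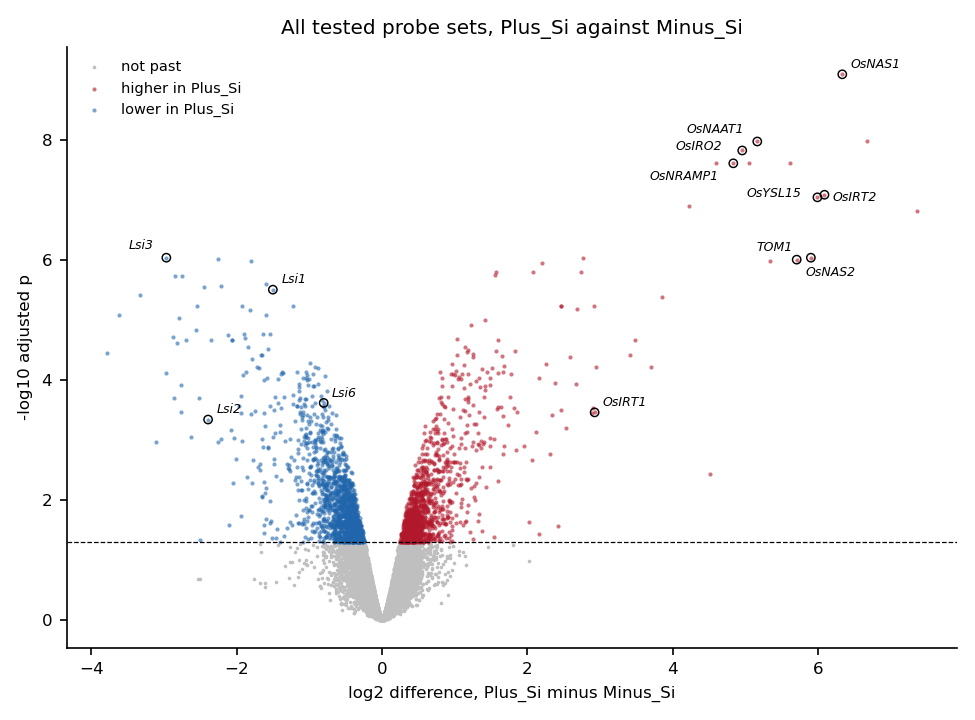
All 45194 tested probe sets by log2 difference, Plus_Si minus Minus_Si (x axis), and by −log10 of the adjusted p from limma (y axis, dashed line at 0.05). Red points are the 1309 probe sets higher in Plus_Si and blue points the 1653 lower; circled points are changed members of the iron and silicon transporter lists, of which the 9 iron genes lie on the right and the 4 silicon transporters on the left.

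Of 12 probe sets for iron and metal uptake genes, 9 rose in Plus_Si and 0 fell, the same counts as when adjusted over the list alone. The list's median log2 difference was 5.06 (4.99 in technical set 1 and 5.12 in set 2), or 4.86 with 2 genes at their lower bound. Rice takes up iron both as the ferrous ion and, bound to secreted deoxymugineic acid, as ferric iron, and the rises covered both routes. OsNAS1 (LOC_Os03g19427) and OsNAS2 (LOC_Os03g19420), neighbouring genes for nicotianamine synthases, rose from 5.50 ± 0.14 and 6.12 ± 0.58 to 11.83 ± 0.15 and 11.82 ± 0.17 on the log2 scale (SD, n = 4 per group). Their transcript clusters lie on chromosome 3 at 10928201 to 10929613 and at 10925187 to 10926668. OsNAAT1, the aminotransferase of the next step, was at least 29.5-fold higher, since all its Minus_Si arrays lay under the background controls. TOM1, which exports deoxymugineic acid, was 59.7-fold higher (adjusted p = 9.19e-07), and OsYSL15, which takes the iron complex back up, was 63.5-fold higher (adjusted p = 9.09e-08). The ferrous iron transporter genes OsIRT1 and OsIRT2 were 7.59-fold and at least 27.8-fold higher. OsNRAMP1, another metal transporter gene, rose by a log2 difference of 4.83 ± 0.13 (SE), and OsIRO2, a transcription factor of the iron deficiency response, by 4.96 ± 0.12 (SE). The rise of OsIRO2 was from a mean of 5.09, just above the range of the background controls. The other 3 members did not pass: the log2 differences were 0.02 for OsHMA2, -0.01 for OsHMA3 and -0.28 for OsNRAMP5, the root's manganese and cadmium importer gene, which was at 10.81 ± 0.16 in Plus_Si and 11.09 ± 0.24 in Minus_Si. The list stood apart from the other probe sets with camera's preset correlation (adjusted p = 2.08e-20) but not with an estimated one (adjusted p = 0.0909 with an estimated correlation).

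All 4 silicon transporter genes were lower in Plus_Si, over all probe sets and adjusted over the list alone. Lsi1 (LOC_Os02g51110, chromosome 2, 31260376 to 31264091), the channel that lets silicic acid into root cells, fell from 12.97 ± 0.09 to 11.47 ± 0.08 on the log2 scale (SD, n = 4), which is 2.83-fold (adjusted p = 3.13e-06). Lsi2 (LOC_Os03g01700, chromosome 3, 429476 to 431876), which moves silicon out of these cells toward the stele, fell from 12.98 ± 0.13 to 10.59 ± 0.62, with a wider spread in Plus_Si (adjusted p = 0.000454). Lsi3 (LOC_Os10g39980) was 7.81-fold lower and Lsi6 (LOC_Os06g12310), a channel best known from xylem unloading in shoots, was 1.74-fold lower (adjusted p = 9.19e-07 and 0.00024). The median of the 4 was -1.95, and -2.01 and -1.88 within the technical sets. Of 3 genes fixed as loci of the Casparian strip and suberin, the barriers of the endodermis and exodermis, 1 rose, also when adjusted over the list alone, and their median log2 difference was 0.33. OsABCG25, a half-size ABC transporter, was 1.25-fold higher (adjusted p = 0.0165), a call that ended in each technical set alone and without Plus_Si replicate 1 or 4. OsCASP1, which organises the Casparian strip, had a log2 difference of 0.52 (95% interval -0.14 to 1.18, adjusted p = 0.334), and RCN1, a transporter needed for the suberin of the exodermis, 0.01 (-0.4 to 0.43, adjusted p = 0.976).

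**Figure D2:**
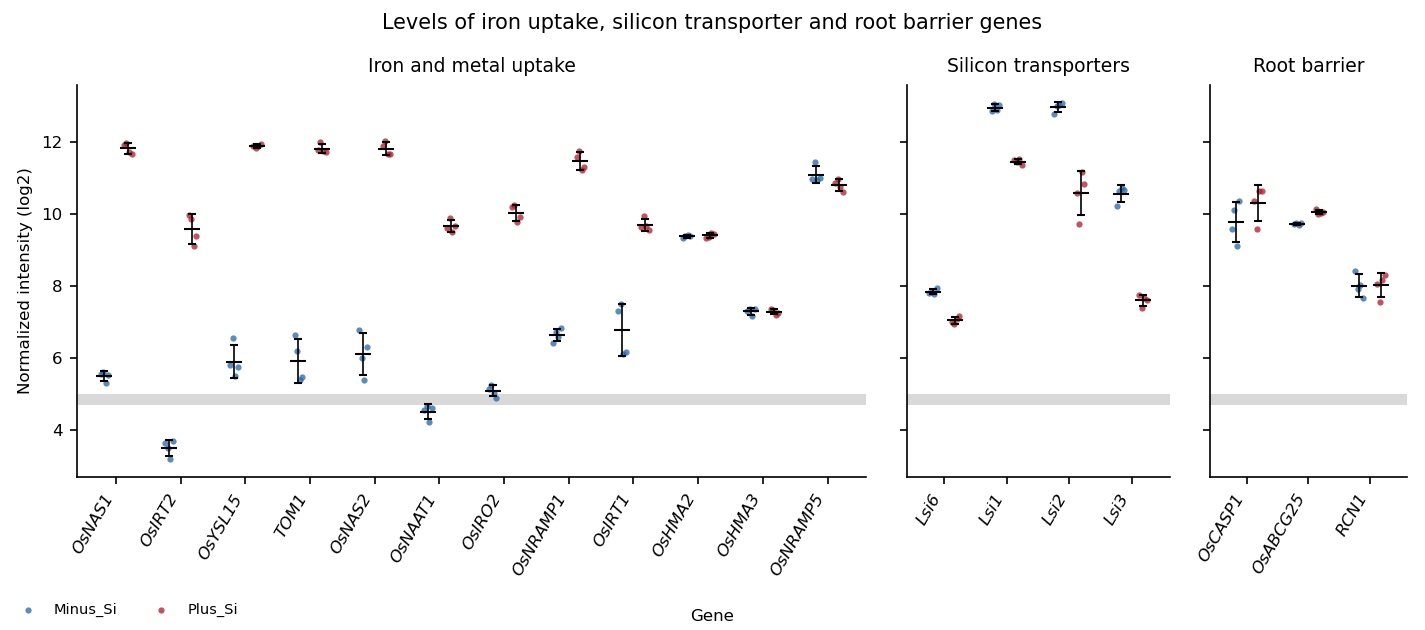
Normalized intensity (log2, y axis) of genes of iron and metal uptake, silicon transport and the root barriers (x axis) in Minus_Si (blue) and Plus_Si (red). Points are the 4 biological replicates per group, horizontal marks with bars their mean ± SD, and the grey band the range over arrays of the median of the background controls, 4.7 to 5. For 9 iron genes the groups are far apart, with OsIRT2 and OsNAAT1 under the band in Minus_Si, while all 4 silicon transporters are lower in Plus_Si.

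Among the 10 rises with the largest fitted differences, 6 were members of the iron list: OsNAS1, OsIRT2, OsYSL15, TOM1, OsNAS2 and OsNAAT1. For 5 of the 10 the Minus_Si arrays lay under the background controls, so their bounds of 20.2-fold to 37.3-fold do not fix their rank against genes such as OsIRO2 (31.0-fold) and OsNRAMP1 (28.5-fold). The Minus_Si mean of OsIRO2, 5.09, itself lay just above the range of the background controls, so its fold is uncertain too. A further rise was that of OsYSL2 (Os02g0649900), which carries nicotianamine complexes of metals and rose 102-fold, from 5.30 ± 0.27 to 11.97 ± 0.24 (SD, n = 4). LOC_Os10g11889, an expressed protein without a described function, was at least 37.3-fold higher. LOC_Os12g18410, also annotated only as expressed, was at least 29.3-fold higher. LOC_Os03g41926, a hypothetical protein whose probes also match other sequences, was at least 20.2-fold higher. The falls included those of the neighbouring genes LOC_Os05g48730 and LOC_Os05g48740 of chromosome 5, with log2 differences of -3.78 ± 0.27 and -3.61 ± 0.21 (SE); neither has a described function. The cytochrome P450 gene LOC_Os08g01450 was at least 6.05-fold lower, and the acyltransferase gene LOC_Os12g27350 8.61-fold lower. LOC_Os09g22000, a hydrolase of the HAD superfamily, was 7.85-fold lower, and LOC_Os08g32840, with a carbonic anhydrase-like annotation, 7.24-fold lower. Lsi3 was also among the 10 falls with the largest fitted differences, as were LOC_Os02g51760, LOC_Os07g44920 and the transferase gene LOC_Os10g01920 with log2 differences of -2.88, -2.84 and -2.82. The Plus_Si means of LOC_Os09g22000, LOC_Os08g32840 and LOC_Os10g01920, 4.86, 4.53 and 4.12, lay within or under the range of the background controls, which leaves the size of these falls uncertain. That of LOC_Os12g27350 was 5.02 ± 0.68 (SD), with replicates 2 and 4 at 4.79 and 4.30, within and under that range. The size of its fall is therefore uncertain too.

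Of 28 probe sets for nitrogen transport and assimilation, 9 rose and 1 fell (13 and 2 adjusted over the list alone). OsNAR2.1 (LOC_Os02g38230), the partner protein of high-affinity nitrate transporters, was 2.50-fold higher, the ammonium transporter gene OsAMT3;3 (LOC_Os02g34580) 2.45-fold and another ammonium transporter gene, LOC_Os02g40710, 2.00-fold, the last from a mean of 4.99 within the range of the background controls. The member that fell was a glutamine synthetase gene, LOC_Os03g12290, by 0.34 on the log2 scale, named after its value was seen. The list was higher with camera's preset correlation (adjusted p = 5.09e-05); the adjusted p = 0.0909 with an estimated correlation. Of 39 aquaporin probe sets, 2 rose and 10 fell (6 and 14 adjusted over the list alone), and Lsi1 and Lsi6 belong to those that fell. The gene of the tonoplast aquaporin OsTIP1;2 (LOC_Os01g74450) was 6.20-fold lower, and that of the plasma membrane aquaporin OsPIP2;3 (LOC_Os04g44060) 3.14-fold lower. The aquaporin list had adjusted p = 0.00864 with the preset correlation and adjusted p = 0.589 with an estimated correlation; without Plus_Si replicate 2 the preset value was 0.0681. Of 9 probe sets for phosphate starvation and uptake, 2 rose and 0 fell (3 and 0 adjusted over the list alone); OsSPX2, a sensor of phosphate status, rose 1.63-fold but not in technical set 1 alone (adjusted p = 0.051), and 1 of the OsPT4 probe sets, whose probes also match other sequences, rose 1.60-fold, while the other (LOC_Os04g10750) did not pass (adjusted p = 0.0824). Over the deposited ontology terms, phosphate ion transport was enriched among the falls, with 6 of 25 lower and 1 higher (adjusted p = 0.0362, one-sided Fisher's exact test). That test takes probe sets as independent. The OsPT4 call ended in both technical sets and without any of the Plus_Si replicates or Minus_Si replicate 3 or 4. Of 109 ABC transporter probe sets, 9 rose and 11 fell (12 and 15 adjusted over the list alone). LOC_Os08g30770 was 2.12-fold higher, and STAR2 (LOC_Os05g02750), part of a transporter needed for aluminium tolerance, was 1.84-fold lower.

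Genes of the wall and its barriers moved both ways. Of 64 probe sets for suberin and wax synthesis, 2 rose and 6 fell (5 and 7 adjusted over the list alone): the ketoacyl-CoA synthase gene LOC_Os02g49920, which elongates fatty acids, was at least 1.52-fold higher, and the cytochrome P450 86A1 gene LOC_Os03g04660 was 1.62-fold lower. Of 54 probe sets for Casparian strip proteins and dirigent proteins, 3 rose and 5 fell (4 and 5 adjusted over the list alone), among them the dirigent genes LOC_Os11g07830 and LOC_Os10g18760 with falls of 1.77-fold and 1.54-fold. Of 30 probe sets for phenylpropanoid and monolignol synthesis, 3 rose and 2 fell, with the same counts adjusted over the list alone; the phenylalanine ammonia-lyase genes LOC_Os11g48110 and LOC_Os04g43800, which open the pathway, rose by 0.59 and 0.56 on the log2 scale, though not in either technical set alone, the first from a mean of 4.91 within the range of the background controls. Of 151 class III peroxidase probe sets, 5 rose and 11 fell (6 and 12 adjusted over the list alone), with LOC_Os01g73170 2.42-fold and LOC_Os08g02110 2.29-fold lower. LOC_Os08g20730 had the largest fitted fall, from 7.21 to a Plus_Si mean of 4.66 under the background controls, which leaves its size uncertain. Of 29 laccase probe sets, 3 rose and 0 fell (6 and 1 adjusted over the list alone), with LOC_Os01g63180 2.28-fold and LOC_Os01g63200 1.77-fold higher. The laccase list had adjusted p = 0.0314 with the preset correlation and adjusted p = 0.589 with an estimated correlation; the preset value was 0.0592, 0.0623, 0.0898 and 0.0897 without Plus_Si replicate 1 or 3 or Minus_Si replicate 2 or 3, and 0.0832 in technical set 1 alone. Of 64 probe sets for wall expansion and hemicellulose, 6 rose and 3 fell (8 and 4 adjusted over the list alone); the expansin gene OsEXPA9 (LOC_Os01g14660) rose 2.27-fold. Of 100 probe sets for cellulose and callose synthesis, 5 rose and 3 fell, with the same counts adjusted over the list alone; LOC_Os10g20090, a cellulose synthase-like gene, was 1.58-fold lower.

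Of 132 probe sets for pathogenesis-related proteins and chitinases, 6 rose and 2 fell, and of 10 for diterpenoid phytoalexins 2 rose and 0 fell, with the same counts in both lists adjusted over the list alone. The thaumatin gene LOC_Os03g45960 was at least 1.09-fold higher and LOC_Os05g39580, of the Bet v I family, 1.49-fold higher. Of 102 WRKY factor probe sets, 8 rose and 5 fell (9 and 6 adjusted over the list alone), with LOC_Os01g43650 1.81-fold higher and LOC_Os05g40070 2.15-fold lower. Of 250 MYB factor probe sets, 6 rose and 10 fell (7 and 10 adjusted over the list alone); OsMYB45 (LOC_Os06g45890) was 2.61-fold higher, from a mean of 4.9 within the range of the background controls, and LOC_Os09g26170 3.83-fold lower. Of 125 NAC factor probe sets, 11 rose and 4 fell (17 and 5 adjusted over the list alone), with LOC_Os06g46270 1.55-fold higher. None of these lists passed with camera.

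Of the hormone lists, abscisic acid and dehydration had 2 rises and 8 falls in 140 probe sets, with the same counts adjusted over the list alone. The abscisic stress-ripening gene LOC_Os02g33820 was 2.62-fold lower and the dehydrin gene LOC_Os03g45280 2.11-fold lower. That list was lower with the preset correlation (adjusted p = 0.0495); the adjusted p = 0.46 with an estimated correlation, and the call ended without Plus_Si replicate 2, 3 or 4 (0.0681, 0.0623, 0.106) or Minus_Si replicate 1 or 2 (0.0861, 0.0845) and in both technical sets (0.103, 0.0842), over all arrays (0.0671), with quantile normalization (0.0716), median centring (0.0505), a trend and robust variance (0.0788) or sample weights (0.0554), without the dimmest probe sets (0.0527) and over type 1 probe sets (0.0707). Of 87 gibberellin probe sets, 2 rose and 3 fell, with the same counts adjusted over the list alone; the gibberellin 2-beta-dioxygenase gene LOC_Os01g55240, which inactivates the hormone, and LOC_Os01g08220, a 3-beta-dioxygenase gene, were 3.09-fold and 2.14-fold lower. Ethylene genes had 4 rises and 6 falls in 71 probe sets (7 and 6 adjusted over the list alone), led by the 2.54-fold fall of LOC_Os04g47810. Auxin genes had 6 rises and 4 falls in 139 (7 and 6 adjusted over the list alone), with OsGH3-2 (LOC_Os01g55940), which conjugates auxin, 1.76-fold higher. Cytokinin genes had 3 rises and 5 falls in 84 (4 and 7 adjusted over the list alone), with LOC_Os01g67770, a two-component response regulator gene, 1.43-fold lower. The cytokinin dehydrogenase gene LOC_Os02g12770 rose from a mean of 4.35, under the background controls, to 5.48, so the size of this rise is uncertain. Jasmonate genes had 2 rises and 2 falls in 58 (2 and 3 adjusted over the list alone), with the oxophytodienoate reductase gene LOC_Os01g27230 2.17-fold lower.

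Among stress lists, hypoxia and fermentation had 4 rises and 4 falls in 20 probe sets (7 and 6 adjusted over the list alone). The non-symbiotic haemoglobin genes LOC_Os03g12510 and LOC_Os03g13140, whose products scavenge nitric oxide, were 5.53-fold and 1.86-fold higher, and the pyruvate decarboxylase gene LOC_Os03g18220 was 1.39-fold higher. The sucrose synthase gene LOC_Os03g22120 was 1.66-fold lower. Of 177 probe sets for heat shock proteins and chaperones, 1 rose and 7 fell (1 and 5 adjusted over the list alone), with LOC_Os05g01950, which is on the list because the deposited annotation names a DnaJ cysteine-rich domain, 2.46-fold lower. Of 85 glutathione S-transferase probe sets, 2 rose and 5 fell (4 and 8 adjusted over the list alone), with LOC_Os07g07320 1.69-fold lower. Of 6 circadian clock probe sets 0 changed in either direction with limma, also when adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05; the smallest adjusted p was 0.105, for LOC_Os11g40610. In all, 6 of 30 tested lists passed with the preset correlation and 0 with an estimated one. The median, the mean and the direction of the test differed in sign for suberin and wax, class III peroxidases, jasmonate, hypoxia, the clock, dividing cells and ribosomal proteins, none of which passed.

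**Figure D3:**
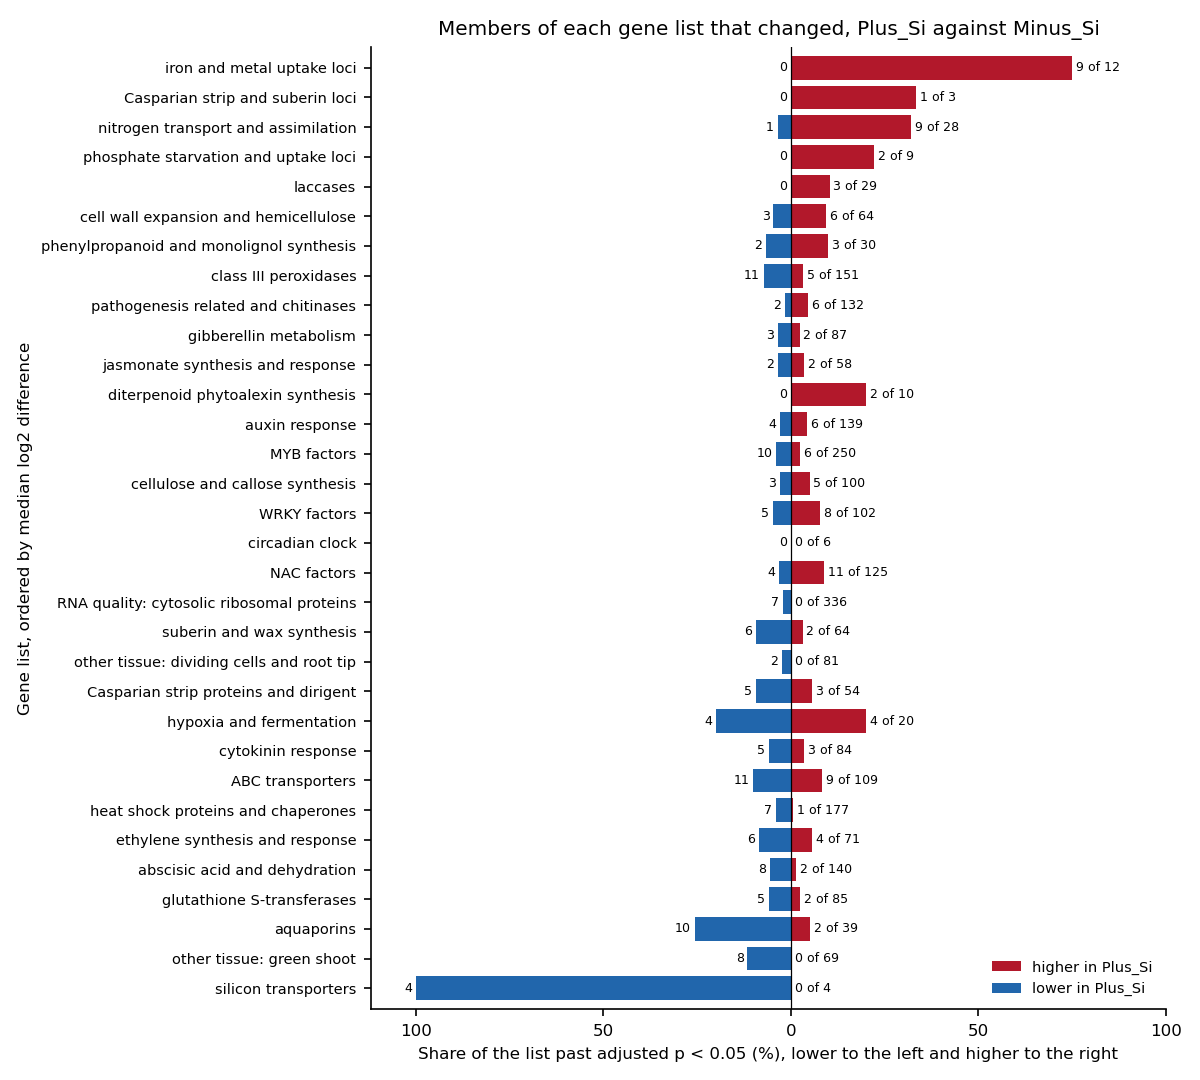
Share of the probe sets of each of the 32 lists (y axis, ordered by median log2 difference) that passed an adjusted p of 0.05 in limma (x axis, %), with rises in Plus_Si to the right and falls to the left of 0. Numbers beside the bars are counts of changed probe sets and of the list; 9 of 12 iron genes rose and all 4 silicon transporters fell.

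Lists of other tissues and of RNA quality were measured beside these groups, since the segment should hold neither root tip nor shoot. Of 81 probe sets for dividing cells and the root tip 0 rose and 2 fell (0 and 1 adjusted over the list alone), with a median log2 difference of 0.01, and 9 were higher and 7 lower at an unadjusted p under 0.05; the histone H3 gene LOC_Os04g34240 was 2.16-fold lower. Of 336 probe sets picked by description as ribosomal proteins, without those that name an organelle, 0 rose and 7 fell (0 and 1 adjusted over the list alone), with a median of 0.02, and 11 were higher and 19 lower at an unadjusted p under 0.05; LOC_Os01g47330, which was 1.31-fold lower, has an L7/L12 domain, known from ribosomes of the bacterial type, so the list is not purely cytosolic. Of 69 green shoot probe sets 0 rose and 8 fell (0 and 12 adjusted over the list alone), with a median of -0.17, and 1 was higher and 21 lower at an unadjusted p under 0.05. The 4 largest falls were in probe sets annotated as photosystem II reaction center protein Z, and the probes of all 4 also match other sequences. Among them LOC_Os01g58038 (1.40-fold lower), LOC_Os04g16876 and LOC_Os02g24628 had nearly the same values in every sample, so their falls are not separate. The other, LOC_Os10g21214, lay under the background controls in every sample of both groups. Of the 8 falls, 5 were on cross-hybridising probe sets. Calls for LOC_Os01g58038 ended in both technical sets and without any of the Plus_Si replicates or Minus_Si replicate 3 or 4. The green shoot list was lower with the preset correlation (adjusted p = 4.03e-05), with adjusted p = 0.589 with an estimated correlation and 0.191 over type 1 probe sets.

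Technical arrays of a sample correlated at 0.99 to 0.9932 across probe sets, which are not independent replicates, and averaged samples at 0.9917 to 0.9955 within a group and 0.9846 to 0.9897 between groups. The first principal component held 46.6% of the variance and separated the groups. The SD between technical arrays of a sample had a median of 0.163 on the log2 scale, and that between averaged samples of a group 0.138. The first is for single arrays and includes any offset between the technical sets. The second is for averages of 2 arrays, so the values cannot be set directly against each other. The deviations of the paired arrays from their group means correlated at 0.22 to 0.37 in Minus_Si samples but at 0.08 to 0.2 in Plus_Si samples, with a consensus correlation of 0.234 over both, so technical noise was a large part of the spread. Of the 2962 changed probe sets, 1581 also passed in technical set 1 alone and 1142 in set 2 alone. Of the 145 named genes that changed, 37 did not pass in set 1 alone and 53 not in set 2 alone; among those given as examples these include LOC_Os01g47330 in set 1 and LOC_Os03g04660, LOC_Os05g40070, LOC_Os02g12770 and LOC_Os07g07320 in set 2.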

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

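Levels of named genes were searched for a sample far from the other 3 of its group, and 10 of 322 groups held one, where chance gives about 1 in 20. All values are log2 intensities, and no explanation was tested. The S-adenosylmethionine synthetase gene among them comes from a list chosen after the main comparison had been seen. In Minus_Si, OsNRAMP5 was at 11.45 in replicate 2 (others 10.95 to 11), the peroxidase gene LOC_Os03g13210 at 6.74 in replicate 1 (others 7.33 to 7.4), the ABC transporter gene LOC_Os04g13220 at 5.86 in replicate 2 (others 6.1 to 6.15) and the thaumatin gene LOC_Os09g36580 at 7.71 in replicate 4 (others 8.19 to 8.24). In the same group, OsGH3-2 (LOC_Os01g55940) was at 7.6 in replicate 3 (others 8.05 to 8.12), the ribosomal protein gene LOC_Os06g23210 at 6.56 in replicate 1 (others 6.89 to 6.95) and the S-adenosylmethionine synthetase gene LOC_Os01g22010 at 9.32 in replicate 4 (others 8.85 to 8.89). In Plus_Si, the ammonium transporter gene LOC_Os02g40710 was at 6.11 in replicate 2 (others 5.94 to 5.96), the oxophytodienoate reductase gene LOC_Os02g35310 at 6.27 in replicate 4 (others 6.48 to 6.51) and the heat shock list gene LOC_Os05g01950 at 6.32 in replicate 1 (others 5.81 to 5.89).

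Of the 7639 intron probe sets that the array carries for normalization, which entered no comparison, 76 passed an adjusted p of 0.05 in limma, 16 higher and 60 lower in Plus_Si, with a median log2 difference of -0.05. Among the 23 antigenomic background controls 0 passed.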

How the results depend on the processing

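The tested probe sets that passed were 2962, 1309 higher and 1653 lower. Of the 35 splits of the 8 samples into 4 and 4, 1, the real one, gave as many, and the highest other split gave 0. That share is under the 0.05 set beforehand, but it is the smallest that 35 splits can give, so it does not exclude chance. The other splits mix the groups, which widens their spread and makes few calls likely. Nor does the test speak to a difference between pots. Among the alternatives, quantile normalization and median centring were mild, since RMA, per the submitters' notes, had already set the distributions of arrays equal. The unrounded values differed from the main ones by rounding only. Counts stayed within 1.5 times those of the main comparison under quantile normalization, median centring, unrounded values, without the dimmest probe sets, with a trend and robust variance, with sample weights and over type 1 probe sets, an alternative chosen after seeing the data (2797 to 3903 in total). They moved further to 1771 (673 higher, 1098 lower) in technical set 1 and 1192 (547 and 645) in set 2, and to 4899 (2006 and 2893) over all arrays with the technical set as a term and the sample as a random block; with a fold of at least 1.5 they were 1150 (489 and 661) by adjusted p and 1267 (540 and 727) by an unadjusted p under 0.01, both of which leave out small changes by construction, and with a plain equal-variance test 1374 (592 and 782). The fit over all arrays took technical arrays as observations, while the groups differ between samples only, so its larger count is no sign of more replication. Leaving out 1 replicate gave 1574 to 3293 in total, 693 to 1622 higher and 881 to 1777 lower. Fewer samples lower the power, and the cause of the differences between replicates was not tested. With the replicate number as a block 1894 passed (783 higher, 1111 lower); same-numbered deviations correlated at -0.04, -0.06, -0.04 and 0.14 and 2 of 8 samples correlated best with their own number, so the numbers were not taken as pairs. Named genes kept direction and call in 2950 cases, lost the call in 545, gained one in 9 and changed sign in 13; lists did so in 536, 27, 4 and 32. The sign changes of genes were in 3 that did not pass: RCN1 (-0.06 in technical set 1, -0.03 and -0.08 without Plus_Si replicate 3 or 4, -0.02 and -0.1 without Minus_Si replicate 2 or 4, and -0.1 to 0.17 over all samples left out), OsHMA3 (0.1 in technical set 2, 0.02 with quantile normalization, 0.02 and 0 without Plus_Si replicate 3 or 4, 0.02 and 0.01 without Minus_Si replicate 2 or 4, and -0.05 to 0.02 over all) and OsSPX3 (0.03 in technical set 2, 0.01 without Plus_Si replicate 4, and -0.08 to 0.01 over all). The lists that changed direction never passed, with these adjusted p: in technical set 2, class III peroxidases 0.907, jasmonate 0.972, circadian clock 0.824, dividing cells 0.687 and ribosomal proteins 0.632; in technical set 1, auxin 0.983; with the replicate block, jasmonate 0.948 and hypoxia 0.948; with quantile normalization, dividing cells 0.903 and ribosomal proteins 0.801; without the dimmest probe sets, Casparian strip and dirigent 0.883, class III peroxidases 0.959, jasmonate 0.883 and ribosomal proteins 0.957; with sample weights, jasmonate 0.992; over type 1 probe sets, auxin 0.927 and ribosomal proteins 0.961; without Plus_Si replicate 1, WRKY 0.958, dividing cells 0.784 and ribosomal proteins 0.441; without Plus_Si replicate 2, class III peroxidases 0.807; without Plus_Si replicate 3 and 4, jasmonate 0.952 and 0.95; without Minus_Si replicate 1, class III peroxidases 0.938, jasmonate 0.98 and auxin 0.925; without Minus_Si replicate 2, jasmonate 0.913; without Minus_Si replicate 3, ribosomal proteins 0.86; without Minus_Si replicate 4, WRKY 0.855, jasmonate 0.948, dividing cells 0.635 and ribosomal proteins 0.525. Over all samples left out these ran from 0.634 to 0.979 for class III peroxidases, 0.615 to 0.958 for WRKY, 0.86 to 0.98 for jasmonate, 0.794 to 0.952 for auxin, 0.432 to 0.954 for dividing cells and 0.11 to 0.954 for ribosomal proteins. The cause was not tested. Wall expansion and hemicellulose passed with adjusted p of 0.0223 in technical set 2, 0.0452 over all arrays, 0.0328 without the dimmest probe sets and 0.0361 without Minus_Si replicate 4, but not otherwise (0.0632 in the main comparison). All list calls ended with an estimated correlation. Signal over background limits dim genes: 75.3% of tested probe sets had a mean above the background controls.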

Other observations

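The gene lists of the next paragraph and the tests on dividing cells, barrier genes and cross-hybridising probes were chosen after the results they bear on had been seen; the tests on iron storage, nuclear photosynthesis and plastid genes were written before their own values were seen, but leaving out iron storage genes under background was decided after.

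Further genes of the iron deficiency response were looked up after the main comparison had been seen and were not tested as a list. OsYSL2 was among the largest rises of that comparison. Of 10 such loci, 7 rose and 2 fell: OsYSL2 102-fold, the transcription factor genes OsIRO3 5.53-fold and OsbHLH133 at least 6.55-fold, the peptide transporter gene OsOPT7 6.44-fold, the deoxymugineic acid synthase gene OsDMAS1 3.20-fold, the nicotianamine exporter gene OsENA1 3.43-fold and OsHRZ1, an iron-binding ubiquitin ligase, 2.09-fold. OsFRDL1, which loads citrate into the xylem, was 1.99-fold lower. OsHRZ2 was 1.44-fold lower, a call that ended without Plus_Si replicate 1, 3 or 4 or Minus_Si replicate 2 or 3. OsIDEF1 had a log2 difference of -0.1 and did not pass. Of 11 probe sets for the methionine cycle and salvage, which supply the precursor of nicotianamine, 5 rose and 0 fell, 2 of the 5 on cross-hybridising probe sets, with the methylthioribose kinase genes LOC_Os04g57410 and LOC_Os04g57400 2.33-fold and 2.28-fold higher.

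Among 691 biological process terms, 10 were enriched among the rises and 34 among the falls (one-sided Fisher's exact test, Benjamini-Hochberg over the terms), on the calls of the averaged samples only. The rises held 7 of 13 probe sets for methionine salvage (adjusted p = 4.49e-05), 8 of 29 for iron ion transport (adjusted p = 0.000792), 88 of 1598 for protein phosphorylation (adjusted p = 0.000714), 6 of 31 for chitin catabolism and 6 of 31 for nitrate transport (adjusted p = 0.0377 for each). In the same order, 1, 4, 64, 1 and 4 members of these terms fell. Iron ion homeostasis held 6 rises (adjusted p = 0.0189) and 5 falls (adjusted p = 0.112) in 24, and cellular iron ion homeostasis was enriched among the falls, with 5 of 16 (adjusted p = 0.0295). Wider metal terms were enriched among the falls and not the rises. Zinc ion transport held 6 falls (adjusted p = 0.0047) and 4 rises (adjusted p = 0.0868) in 16. Metal ion transport held 15 falls (adjusted p = 0.0448) and 8 rises (adjusted p = 0.751) in 126. The falls held 28 of 190 probe sets for photosynthesis (adjusted p = 6.03e-05), 23 of 118 for thylakoid membrane organization (adjusted p = 1.18e-05), 13 of 62 for carotenoid synthesis (adjusted p = 0.000841), 8 of 23 for abscisic acid synthesis (adjusted p = 0.000828) and 11 of 61 for iron-sulfur cluster assembly (adjusted p = 0.0104). Terms share members, so they are not separate findings. Fisher's exact test also takes probe sets as independent. Camera estimated correlations between members of 0.345 for the iron list and 0.243 for the green shoot list. Where members of a term are correlated in this way, its p-value is too small.

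Of 12 iron and metal uptake probe sets 9 rose in Plus_Si, though the list did not pass with an estimated correlation (adjusted p = 0.0909). A larger share of root tip cells was argued against by the dividing cell list, whose median log2 difference was 0.01 with quartiles of -0.06 and 0.08 against 5.06 for the iron list. By the deposited annotation all 12 probe sets of the iron list have type 1, whose probes match 1 target. The count of cross-hybridising probe sets among the 9 that rose was therefore fixed at 0. That count is no test of shared signal between paralogs beyond the annotation itself. For a lower iron status of Plus_Si roots, the rule set beforehand asked for an iron storage median below 0 with at least 2 members lower. The 4 probe sets (ferritins and vacuolar iron transporters) met it, with a fitted median of -0.45 and with OsFER2 and OsVIT2 lower. OsFER1, on a cross-hybridising probe set, lay under background in both groups (2.37 and 2.84, adjusted p = 0.0547 in limma). Without it and with OsVIT2 at its bound the median was -0.23. The rule was met in this form too. It did not ask about OsVIT1, which did not fall, or about the stability of calls, which the OsVIT2 call lacked. Given these 2 points, weighed after the values were seen, the storage genes alone do not tell a lower iron status from an unchanged one. OsFER2 was 1.35-fold lower, though not in technical set 2 alone, OsVIT1 had 0.25, and the OsVIT2 call, at least 1.17-fold lower, ended in both sets and without any of the Plus_Si replicates or Minus_Si replicate 3. Whether silicon supply, another difference between the solutions or a difference between pots lies behind the rise stays open, as untested.

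Silicon transporter genes fell together, with a median of -1.95. A smaller share of exodermis and endodermis, the layers that hold Lsi1 and Lsi2, may be set against OsCASP1, RCN1 and OsABCG25. Their median was 0.33 and their 95% intervals all lie above -1, so they did not fall with the transporters. OsABCG25 was itself called higher, and a rise of such genes could hide a smaller share, so they do not decide the question. All 4 silicon transporter probe sets have type 1 in the annotation. The count of cross-hybridising ones was therefore fixed at 0 and is no further test of shared signal between paralogs. The silicon transporter list was fixed before the data were examined, but the comparison with barrier genes was chosen after its fall was seen. A response of the genes to silicon supply, the difference that the design names, therefore remains a hypothesis. Another difference between the solutions or a difference between pots stays open as well, as untested.

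Some photosynthesis transcripts were lower in Plus_Si, 8 of the 69 green shoot probe sets, 5 of these on cross-hybridising probe sets. That list did not pass in camera with an estimated correlation (adjusted p = 0.589) or over type 1 probe sets (adjusted p = 0.191). Green tissue among the Minus_Si samples is argued against by 22 nuclear light-harvesting and Rubisco small subunit probe sets, abundant in leaves, whose median log2 difference was -0.05 and whose median level in Minus_Si, 4.73, was that of the background controls; the set medians were 0.01 and -0.12. Of the 22, 0 rose and 1 fell, the chlorophyll a-b binding gene LOC_Os07g38960 (1.38-fold lower, adjusted p = 0.0324), a call that ended in both technical sets and without Plus_Si replicate 1, 3 or 4 or Minus_Si replicate 2 or 3; traces too faint to lift these genes stay open. The 154 probe sets of the chloroplast genome had a median log2 difference of -0.15 (quartiles -0.3 and -0.09), with 25 lower and 0 higher. The 76 of the mitochondrial genome had a median of -0.05 (quartiles -0.16 and 0), with 6 lower and 0 higher. A change of plastid transcripts as a whole cannot be told apart from a change of some of them, because the chloroplast median lies between the bounds set for the test.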
